A study of Oryza sativa Japonica Group with 4 samples.

How the data were processed

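Whole seedlings of japonica rice were the material, with total RNA labelled in Cy3 or Cy5 and hybridised as AHX-treated against untreated RNA on 4 arrays, per the labels. The arrays were of Agilent design 015241 (44K rice), and per the file headers they lay on 1 slide and were scanned in 1 session, so that slide and scan could not act as batches between groups. The deposited scanner files give the mean intensity of each spot and the median intensity of its local background in both channels, extracted by the authors with Feature Extraction 9.5.3.1 per the file headers. The series' design text names another version of that software, and which of them made the values could not be settled. The same deposited files give processed intensity, which per the file headers is background-subtracted, spatially detrended and dye-normalized by a linear and a LOWESS step, and a log10 ratio of Cy5 over Cy3 made from it. The deposited series table holds log10 ratios by the authors. On comparison with the scanner files these equal the software's ratio turned to AHX over control on each of the 4 arrays, with a largest deviation of 0.00473 to 0.00498 and column medians of 0 on 3 arrays and 0.000776 on the remaining array, so its scale, centring and direction were settled. Flags of 0 or 1 for signal well above background, saturation and outlying spots were used as the authors deposited them.

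From the mean and background intensities, the background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3 with the data.table package (1.17.8), and each array was normalized by loess with control spots at weight 0. Of 45151 spots, 2007 control spots were left out, as were 6 to 14 spots per array marked as outliers. The remaining 43144 spots stood for 42418 probes of 29695 loci, and spots of 1 probe were averaged. Each log2 ratio was turned to AHX over control by the dyes in the labels. Probes counted in a comparison when they were well above background on every array used in the treated or in the control RNA. Product names are those of the array design, 27358 probes carried an informative name, and 0 loci and 0 accessions matched the reference of gene symbols, so names may be old. Loci are given by the identifiers in the files, whose first digits name the chromosome, and genome coordinates were not used here. A locus was represented by its probe with the highest mean signal. Where the other probes of a named locus went the other way, the text says that they disagree. A probe that was not well above background on any array of 1 of the 2 RNAs has only a bound, given as "at least N-fold": the mean of the bright RNA against the higher of the dim probe's value and the lowest signal among probes well above background, taken per channel after loess and Aquantile normalization.

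The labels call the 2 arrays of a dose dye swaps of each other, so they were averaged to 1 replicate per dose, and the SD between them was taken to cover labelling and hybridisation only. The design text also speaks of separately grown plants with a single replicate on each array, which leaves open whether the swapped arrays carried the same RNA. The titles give the numbers 1 and 2 to the doses, for treated and untreated seedlings alike, so a separate control sample for each dose is not ruled out by the labels. Here replicate 1 of a dose means the array with AHX in Cy5 and replicate 2 the array with AHX in Cy3. The control RNA was treated as 1 sample for both doses. With the dye direction taken out, the control channels of the 2 doses differed with an SD of 0.117 and 0.0538 log2 units in the 2 dye orientations, these differences correlated at r = 0.051 across 36052 probes, and 0 probes differed 2-fold in both. The treated channels differed with an SD of 0.333 and 0.325, correlated at r = 0.917, and differed 2-fold in both at 417 probes. The comparisons were AHX against control at each dose, over both doses, and between the doses. For a single dose, and for the difference between doses, probes were counted when the ratio was at least 2-fold in the same direction on both arrays or in both dye orientations, with no p-value. Over both doses, limma's lmFit and eBayes (with an intensity trend) tested the 2 dye-swap averages against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual and 4.1 prior degrees of freedom. Its p-values measure the spread between the 2 treated samples and leave out that of the control. Those samples are the 2 doses, so a difference between the doses counts as spread and raises the p-value.

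The tests, the filters, 37 gene lists matched by product name and the alternative settings were fixed before the data were examined. The lists of glutathione S-transferases, proteinase inhibitors, aquaporins and jasmonate synthesis were written with knowledge of what the study had reported on these arrays. A list needed at least 5 measured loci. Each list's median at a dose was placed among 10000 random lists of the same size drawn within 20 bins of mean signal (seed 1), and over both doses the lists were tested with limma's camera, first with a preset and then with an estimated correlation between genes. The estimated form takes its degrees of freedom from the 2 treated samples, which leave 1, so after adjustment it could hardly pass any list. Genes were named by rule: per dose the 12 highest and 12 lowest probes with an informative name and a 2-fold ratio on both arrays, over both doses the 15 highest and 15 lowest past the threshold with a mean of at least 2-fold, between doses the 6 highest and 6 lowest, per list the 2 highest and 2 lowest members, and in addition the xanthine dehydrogenase, 12-oxophytodienoate reductase, Bowman-Birk inhibitor and tonoplast aquaporin probes. Families and chromosomal runs in the closing section were picked after their values were seen.

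The steps were tested on simulated data over 36988 probes, with 100 probes changed per size. At a log2 ratio of 1, the 2-fold rule recovered 15% of changed probes at 0.05 mM and 26% at 0.2 mM, and limma over both doses recovered 34%. At a log2 ratio of 2 these shares were 100, 100 and 99%. A true log2 ratio of 1 lies on the 2-fold threshold itself, so each array passed or failed about equally often whatever its spread. The shares of 15 and 26% therefore follow from the threshold, do not rank the doses and cannot be set against limma's. Among unchanged probes the rules made 0, 0 and 6 calls. The 2-fold rule was simulated with the spread between arrays alone, so its 0 calls leave out any spread between seedling samples. In 20 simulations without any effect, limma over both doses made a median of 0 and at most 3 calls with independent ratios, but a median of 77 and at most 902 calls when 1 control sample entered both ratios. The control was given the spread of a treated sample, taken from the difference between the doses, and its true spread is not known. A list shifted by 0.2 log2 units lay at percentile 100 and had an adjusted p of 6.54e-16 by camera with a preset correlation, and 0 unshifted lists passed. These lists held random probes with independent ratios. False list calls with a shared control or with correlated genes were not simulated. Alternatives tried were Agilent's processed signals, the deposited series table, no background correction, normexp with offset 0, median centring, Aquantile normalization, 4 filters on probes (none, the submitters' minimum of 300 for the control in Cy3, signal well above background in both channels of every array, and no saturated probes), arrays left out in turn or taken as separate replicates, and other forms of the limma fit. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The 510 microRNA probes of the array were kept among all probes, and 155 of them were well above background.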

Results

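Seedlings of rice (Oryza sativa, japonica) were kept from germination for 2 weeks with 2-azahypoxanthine (AHX), a purine analogue known from the fungi behind fairy rings in grass, at 0.05 or 0.2 mM, or without it. Transcript levels in whole seedlings were read on 4 arrays of 2 colours, each carrying treated RNA in 1 dye and untreated RNA in the other. Every dose had 2 arrays with the dyes exchanged, which count as 1 treated sample, and the untreated RNA counts as 1 sample for both doses. Errors written with ± are the SD between the 2 arrays of a dose (n = 2 arrays). By the labels they hold no variation between plants, though the design text leaves open whether swapped arrays carried the same RNA. Median spot intensity was 713 to 766 in Cy3 and 1816 to 2052 in Cy5 over a local background of 42 to 55, between 85.9 and 89.2% of 42418 rice probes were well above background, and 0 spots were saturated. Across probes, which are not independent replicates, the log2 ratios of the 2 arrays correlated at r = 0.729 for 0.05 mM and r = 0.855 for 0.2 mM. The number of arrays limits the precision of every value.

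The lower dose was compared with untreated seedlings to see which transcripts differ at 0.05 mM. Thionins, small antimicrobial peptides of cereals, were among the highest: the log2 ratio was 3.08 ± 0.32 for Os06g0514100, 2.73 ± 0.12 for the phoratoxin gene Os06g0514800 and 2.14 ± 0.088 for Os06g0512700. Alpha-amylase isozyme 3E (Os08g0473600), of a family that breaks down starch, was at 2.21 ± 0.12 and a methyl chloride transferase (Os03g0843800) at 1.71 ± 0.34. Peroxidase 1 (Os07g0639000), of the secreted haem peroxidases, was at 2.06 ± 0.26. A glutathione S-transferase (Os03g0785900), of the enzymes that couple glutathione to foreign or toxic compounds, was at 2.04 ± 0.045 and an FAD-dependent oxidoreductase (Os08g0519100) at 1.99. An extensin-like protein of the cell wall (Os05g0552600) was at 1.92 ± 0.071, an esterase (Os04g0449800) at 1.91 ± 0.021 and an aspartic peptidase (Os01g0936900) at 1.76. Lower than in untreated seedlings were 2 nicotianamine synthases, which make the precursor of the chelators that grasses use to take up iron, at -2.21 ± 0.001 (Os03g0307200) and -2.05 ± 0.014 (Os03g0307300). Allene oxide synthase (Os02g0218700), which commits lipid peroxides to jasmonate synthesis, was at -1.92 ± 0.25.

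The lowest named ratio at 0.05 mM was that of a beta-glucosidase aggregating factor (Os12g0198700) at -2.65 ± 0.018, and a second gene of that name (Os12g0247700) was at -1.94. A terpene synthase (Os04g0344100), of the enzymes that form terpenoid skeletons, was at -2.30 ± 0.019. A PGPS/D12 protein (Os03g0830500) was at -2.30 ± 0.17 and a multicopper oxidase (Os12g0258700) at -2.27 ± 0.046. An aminotransferase-like protein (Os02g0112900) was at -2.04 ± 0.024, an ABC transporter (Os08g0544400) at -1.92 ± 0.16 and an expansin-related protein (Os09g0472900) at -1.82 ± 0.084. Of 37321 probes measured at this dose, 87 were at least 2-fold higher and 118 at least 2-fold lower on both arrays (66 and 89 loci). A 2-fold deviation with the dye on both arrays was found at 0 probes. With 1 treated sample the ratios have no replicate check beyond the dye swap. Agilent's processed signals gave 519 probes (263 higher, 256 lower), the deposited values 518 and normexp with offset 0 gave 328, while the single array without replicate 1 gave 349.

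At 0.2 mM, the higher dose against untreated seedlings, the lowest ratios included hydrolases and defence genes. A cysteine endopeptidase (Os01g0907600), a protein-degrading enzyme, had a log2 ratio of -4.69 ± 0.33 and a multicopper oxidase (Os12g0258700) -4.22 ± 0.023. The nicotianamine synthases were at -3.80 ± 0.041 (Os03g0307200) and -3.26 ± 0.12 (Os03g0307300). Pathogenesis-related protein 1 (Os01g0382000), a marker of defence responses, was at -3.76 ± 0.26. An alpha-amylase (Os02g0765600) was at -3.69 ± 0.073 and a subtilase (Os02g0269600), a serine protease, at -3.38 ± 0.011. Of the terpene synthases, Os12g0491800 was at -3.26 ± 0.017 and Os04g0344100 at -3.22 ± 0.24. Allene oxide synthase (Os02g0218700) was at -3.15 ± 0.46 and an antifungal alpha-amylase and trypsin inhibitor (Os03g0661600) at -3.05 ± 0.001. Above the control were the glutathione S-transferase genes Os09g0367700 at 2.85 ± 0.27, Os03g0785900 at 2.50 ± 0.036 and Os10g0528300 of the tau class at 2.12 ± 0.010 (0.60 for the weakest of its 3 probes). The peroxidases Os07g0639000 at 2.50 ± 0.31 and Os04g0423800 at 2.15 ± 0.033 lay above it too.

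Further genes above the control at 0.2 mM were aquaporin TIP2.1 (Os02g0658100), a water channel of the vacuolar membrane, at 2.36 ± 0.065 and expansin EXPA3 (Os05g0276500), which loosens cell walls, at 2.09 ± 0.027. A gene named for the auxin efflux carrier PIN2 (Os06g0660200) was at 2.07 ± 0.31. Neighbouring genes that the array design names eggshell proteins were at 2.63 ± 0.16 (Os10g0452900), 2.43 ± 0.37 (Os10g0453900) and 2.37 ± 0.020 (Os10g0454500). Near them, Os10g0452500, named a glycine-rich protein precursor, was at 2.05. Some transcripts were not well above background in 1 of the RNAs and have only a bound. The control was brighter by at least 5.32-fold for an agmatine coumaroyltransferase (Os04g0664500), 4.16-fold for a cytochrome P450 (Os07g0218700), 3.27-fold for a germin (Os09g0568500) and 3.23-fold for an alpha-amylase (Os02g0765400). AHX was brighter by at least 3.55-fold for another eggshell-named gene (Os10g0455100) and 2.08-fold for a non-symbiotic haemoglobin (Os03g0234100). Of 37402 probes measured, 207 were at least 2-fold higher and 523 at least 2-fold lower on both arrays (174 and 374 loci, 28.4% of probes higher). Again 0 probes deviated 2-fold with the dye on both. Agilent's processed signals gave 632 higher and 901 lower (41.2% higher) and the deposited values 630 and 901 (41.1%), so the share of higher probes depended on the scaling. As at 0.05 mM, 1 treated sample gives no replicate check and no p-value.

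**Figure D1:**
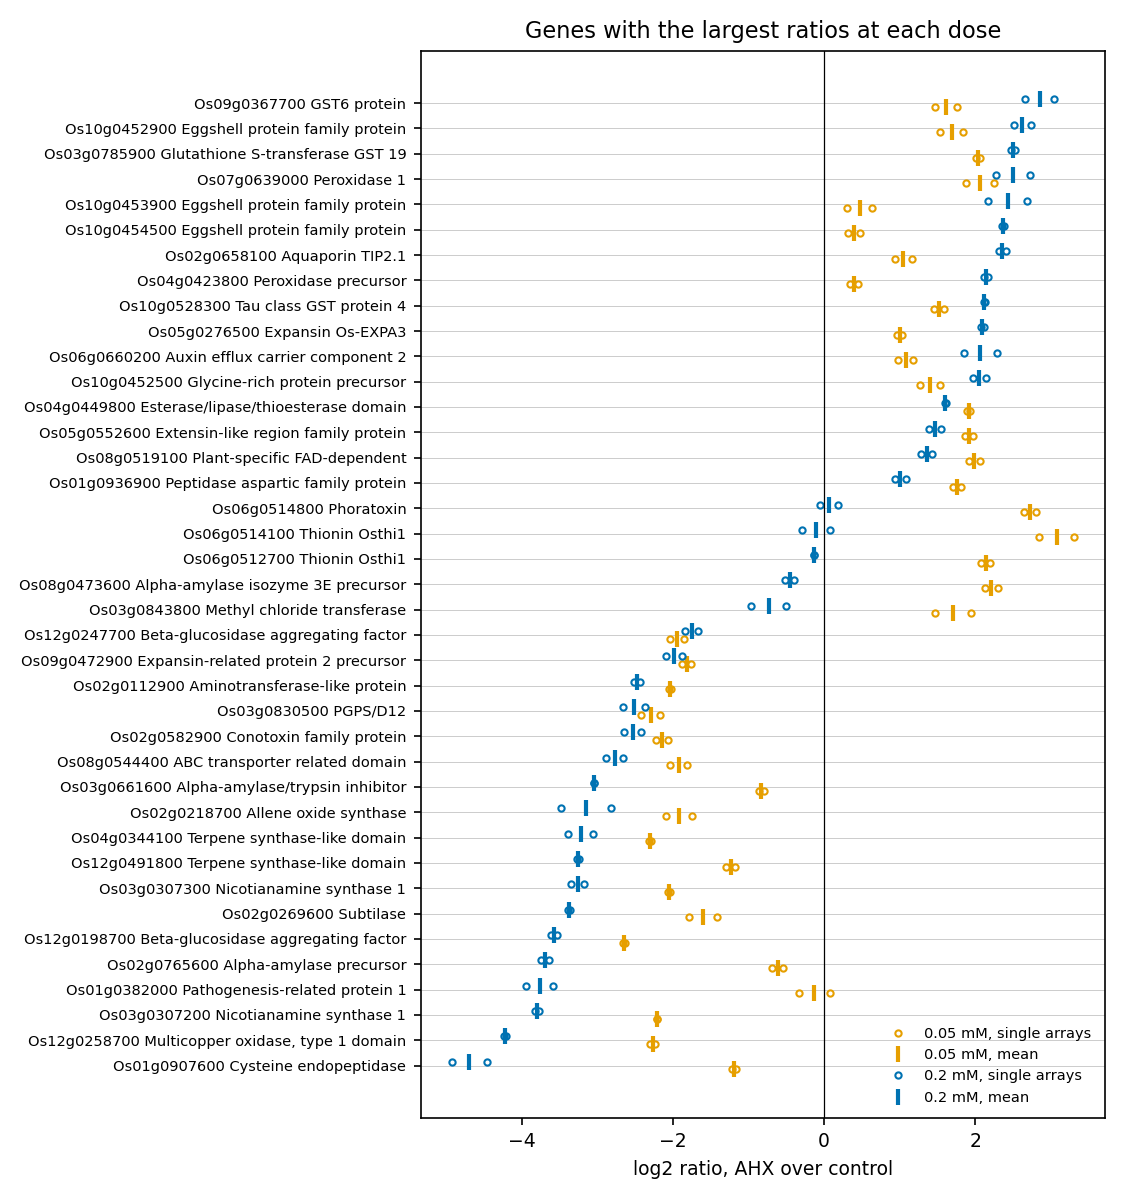
Log2 ratio of AHX over control for the genes with the highest and lowest ratios at either dose (horizontal axis, log2 units; 1 gene per line), with circles for the 2 single arrays of a dose and bars for their mean, orange at 0.05 mM and blue at 0.2 mM. Thionin Os06g0514100 lies at 3.08 at 0.05 mM and -0.11 at 0.2 mM, and cysteine endopeptidase Os01g0907600 at -1.19 and -4.69.

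The ratios of both doses were then tested together for genes that differed from the control alike at 0.05 and 0.2 mM. Among genes that rose, peroxidase 1 (Os07g0639000) had a mean log2 ratio of 2.28 (SE 0.15, n = 2 treated samples, limma adjusted p = 0.0446). The glutathione S-transferases had 2.27 for Os03g0785900 (SE 0.13, limma adjusted p = 0.0446), 1.82 for Os10g0528300 (SE 0.17, limma adjusted p = 0.0466) and 1.62 for Os10g0527400 (SE 0.11, limma adjusted p = 0.0446). The weakest of 3 probes of Os10g0528300 was at 0.52 at 0.05 mM and 0.60 at 0.2 mM. The Bowman-Birk proteinase inhibitor D-II (Os01g0127600), which blocks serine proteases, had 1.71 (SE 0.16, limma adjusted p = 0.0466). An esterase (Os04g0449800) rose by 1.76 and an extensin-like protein (Os05g0552600) by 1.69. A UDP-glycosyltransferase (Os07g0510500), of the enzymes that attach sugars to small molecules, rose by 1.34 and a peroxiredoxin (Os07g0638400), which removes peroxides, by 1.18. The beta-glucosidase aggregating factor Os12g0198700 fell by 3.11 (SE 0.24, limma adjusted p = 0.0446), terpene synthase Os04g0344100 by 2.76 (SE 0.24, limma adjusted p = 0.0466) and the ABC transporter Os08g0544400 by 2.35 (SE 0.22, limma adjusted p = 0.0466). A protein of the family named purine and other phosphorylases (Os05g0228000) fell by 1.98 (SE 0.17, limma adjusted p = 0.0466) and the germin-like protein Os08g0189900 by 1.94 (SE 0.13, limma adjusted p = 0.0446).

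Others that fell over both doses, given as log2 ratios at 0.05 and 0.2 mM, were germin-like proteins Os08g0189600 (-1.58 and -2.00) and Os08g0231400 (-1.81 and -1.73). So did the ZIM-domain proteins Os10g0391400 (-1.45 and -2.07) and Os03g0180800 (-1.43 and -1.99), of a family that represses jasmonate signalling, and WRKY transcription factor Os12g0116700 (-1.21 and -1.50). The chitinases Os01g0660200 (-1.24 and -1.29) and Os03g0132900 (-1.19 and -1.30), which degrade fungal cell walls, and asparagine synthetase Os03g0291500 (-1.09 and -1.25) fell as well. The nicotianamine synthases missed the threshold (limma adjusted p = 0.063 for Os03g0307200 and 0.0554 for Os03g0307300), as did allene oxide synthase Os02g0218700 at -2.54 (limma adjusted p = 0.0618). In that order, their ratios differed by -1.591, -1.205 and -1.229 between the doses (0.2 minus 0.05 mM), which this test counts as spread. Of 36988 probes, 38 rose and 65 fell (30 and 50 loci, limma adjusted p 0.0446 to 0.0492), and 7641 had an unadjusted p under 0.05. With 1 control sample in both ratios and no effect at all, simulations gave a median of 77 and at most 902 calls. They gave the control the spread of a treated sample. The 103 calls did not exceed what a shared control of that spread can give, and its true spread is not known. With Agilent's processed signals limma made 0 calls (7636 at an unadjusted p under 0.05, lowest adjusted p 0.0538). Limma made 0 calls too when the control was taken to vary like a treated sample (2049 at an unadjusted p under 0.05).

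Ratios at the 2 doses correlated at r = 0.553 across 36988 probes. In 100 simulations of a shared control without effects r was 0.501, a value fixed in advance by giving control and treated samples equal spread. The covariance of the ratios was 0.0579 against 0.0378, the latter fixed by taking every ratio at 0.05 mM as spread between samples. The true spread of the control is not known, so neither comparison separates effects from a shared control. Of probes at least 2-fold higher, 87 at 0.05 mM and 206 at 0.2 mM, 38 were shared. Of those at least 2-fold lower, 118 and 523, 94 were shared. Among the shared genes were peroxidase 1, the glutathione S-transferase Os03g0785900 and the nicotianamine synthases. The untreated sample could not be split, so how many shared probes a common control alone would give was not tested.

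**Figure D2:**
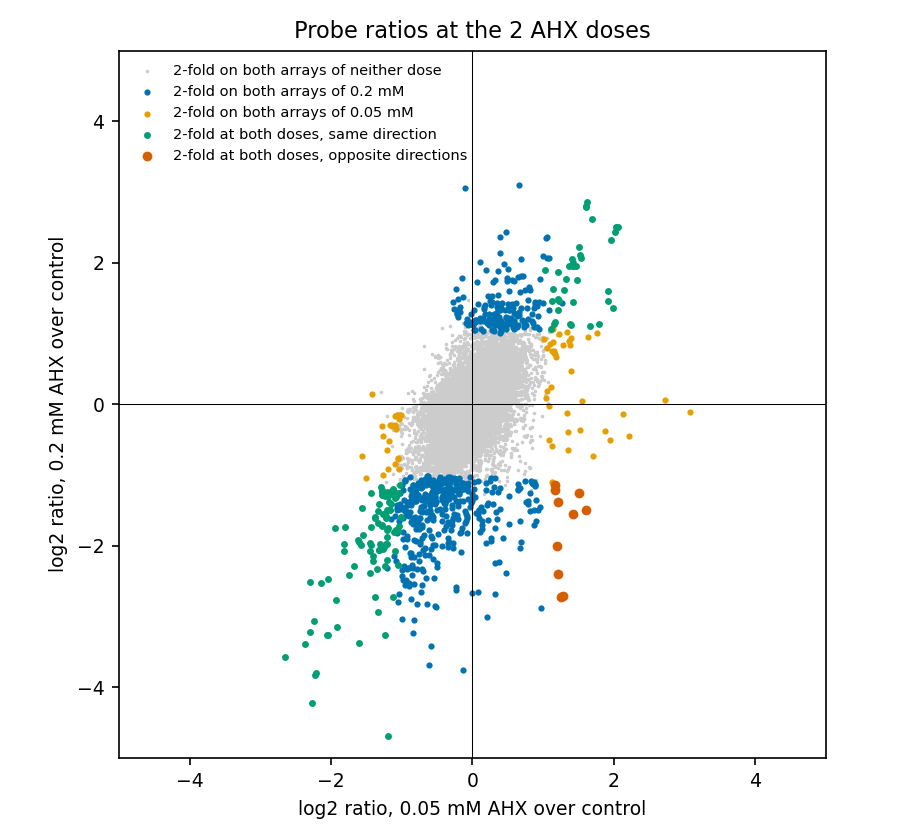
Log2 ratio of AHX over control at 0.05 mM (horizontal axis) and 0.2 mM (vertical axis) for 36988 probes, each point the mean of 2 dye-swap arrays, coloured by whether both arrays of a dose were at least 2-fold. At both doses 38 probes were higher and 94 lower, and 10 were higher at 0.05 mM and lower at 0.2 mM.

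The doses were then set against each other gene by gene. A proline-rich protein (Os06g0168700) was 1.28 ± 0.29 at 0.05 mM and -2.72 ± 0.14 at 0.2 mM. A homeobox protein (Os03g0727000), of a class of developmental transcription factors, was at 1.25 ± 0.015 and -2.73 ± 0.063, and a germin (Os09g0568700) at 0.96 ± 0.029 and -2.88 ± 0.27. The dose difference (0.2 minus 0.05 mM, ± SD between dye orientations) was -3.64 ± 0.025 for pathogenesis-related protein 1 (Os01g0382000), -3.50 ± 0.29 for cysteine endopeptidase Os01g0907600 and -3.22 ± 0.069 for a xylan endohydrolase (Os05g0298700), which cleaves a cell wall polymer. Higher at 0.2 mM were the eggshell-named genes Os10g0454500 by 1.97 ± 0.091 and Os10g0453900 by 1.96 ± 0.60, the latter with a control that was not well above background at 0.05 mM. A dirigent protein of the lignan pathway (Os07g0638500) was higher by 1.91 ± 0.15 and lipoxygenase L-2 (Os03g0738600), which oxidises fatty acids, by 1.86 ± 0.014. Peroxidase Os04g0423800 was higher by 1.75 ± 0.041 and an Ole e 1 domain protein (Os10g0546100) by 1.67 ± 0.062. The thionin Os06g0514100 was at 3.08 at 0.05 mM and -0.11 at 0.2 mM, and alpha-amylase 3E Os08g0473600 at 2.21 and -0.45.

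Of 36997 probes, 114 were at least 2-fold higher and 335 at least 2-fold lower at 0.2 than at 0.05 mM in both dye orientations (95 and 239 loci). The difference had an SD of 0.324 log2 units over probes, with a technical SD of 0.0504. The 10 probes that were 2-fold higher at 0.05 mM and 2-fold lower at 0.2 mM stood for 5 loci, and 0 probes went the other way. These are the proline-rich protein Os06g0168700, homeobox protein Os03g0727000, a lectin (Os04g0173800), a gene named for the large Rubisco chain (Os04g0516200) and an alpha-amylase (Os08g0473900), listed after their values were seen. With 1 treated sample per dose the difference was not tested. Agilent's processed signals and the deposited values both gave 911 probes and normexp with offset 0 gave 708.

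Gene lists were compared next, to see which groups moved together. Transcripts for cytosolic ribosomal proteins, which build the translation machinery, were higher at both doses, with a median log2 ratio of 0.28 ± 0.067 at 0.05 mM and 0.26 ± 0.075 at 0.2 mM over 149 loci. Of these, 144 loci lay above 0 at 0.05 mM and 138 at 0.2 mM, and 60S protein L38 (Os11g0433900) was at 0.68 and 0.71. The list holds 2 products named mitochondrial (Os03g0725000 and Os12g0524700), and its medians were 0.28 and 0.26 over the 147 loci without them. Genes for DNA replication and the cell cycle had medians of 0.12 and 0.15 over 97 loci, with histone H4 (Os02g0684500) at 0.74 and 0.78. The 1 member 2-fold higher at 0.2 mM, Os10g0463600, is named a reverse transcriptase, an enzyme of mobile elements. So are 8 of the 97 loci in all, without which the medians were 0.12 and 0.14. Both lists passed camera (limma adjusted p = 1.07e-20 and 6.34e-05 with a preset correlation). With an estimated correlation camera gave adjusted p = 0.826 for both, a form that could hardly pass any list with 2 treated samples. No single member rose over all probes, and 10 and 23 rose when adjusted over the list alone. Counts adjusted over a list alone, here and below, were not set against random lists. Of all 36988 probes, 7641 had a limma unadjusted p under 0.05, so such counts are no separate support for a list. Housekeeping genes (116 loci, actins, tubulins and the like) had medians of 0.084 and 0.11 and passed too (limma adjusted p = 0.00515 preset, adjusted p = 0.826 with an estimated correlation). Here 0 members passed limma over all probes and 8 rose when adjusted over the list alone. A SUMO-conjugating enzyme (Os04g0580400) was at 0.85 and 1.15.

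Defence lists had medians below the control at 0.2 mM and closer to it at 0.05 mM. Pathogenesis-related proteins had a median of -0.057 ± 0.062 at 0.05 mM and -0.19 ± 0.060 at 0.2 mM over 136 loci, with 4 and 30 loci 2-fold lower and 0 higher at either dose. Chitinase Os05g0399400 was at -1.46 and -2.38, while thaumatin-like Os10g0146200 was at 0.91 and 0.74. Among 70 WRKY factors, regulators of defence genes, the median was -0.061 and -0.23, with 2 and 4 loci 2-fold lower. The 14 ZIM-domain repressors of jasmonate signalling had medians of -0.22 and -0.73, with 2 and 4 loci 2-fold lower. The 38 proteinase inhibitors had medians of -0.022 and -0.21, with 3 and 8 lower and 1 higher at each dose. Camera with a preset correlation put all 4 lists below other genes (limma adjusted p = 0.00503, 0.000559, 0.0037 and 0.0377), and adjusted p = 0.826 for each with an estimated correlation, which could hardly pass any list. Without the filter the inhibitors did not pass (limma adjusted p = 0.108). Over all probes 2 pathogenesis-related, 1 WRKY and 2 ZIM-domain loci fell and 1 inhibitor rose. Adjusted over the list alone, 33, 12, 9 and 12 fell and 6, 2, 1 and 1 rose.

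Within the Bowman-Birk family, serine protease inhibitors, the D-II gene Os01g0127600 was at 1.43 ± 0.15 and 2.00 ± 0.11, while neighbouring genes were lower: Os01g0123900 at -1.08 and -1.78, Os01g0124100 at -0.94 and -1.57, Os01g0124200 at -0.81 and -1.65, and Os01g0124400, whose probes disagree, at -0.90 and -1.58. For Os01g0124000 the control was brighter by at least 1.86-fold at 0.2 mM. Os01g0132000 was at -0.92 and -0.19 and Os03g0823400 at -0.40 and -0.19. In jasmonate synthesis (23 loci, medians -0.029 and -0.050, limma adjusted p = 0.617), 0 members passed limma over all probes and adjusted over the list alone 1 rose and 3 fell. The loci named 12-oxophytodienoate reductases were at 0.14 and 0.12 (Os02g0559400), 0.38 and -0.10 (Os06g0215600), 0.69 and 0.31 (Os06g0216300) and 0.12 and 0.021 (Os08g0459600). The name alone does not settle which of them act in jasmonate synthesis. Because the study reported on inhibitors, glutathione S-transferases, aquaporins and these reductases from the same arrays, their counts are not independent evidence of direction. For diterpenoid phytoalexins, antimicrobial compounds of rice, the name pattern matched 2 measured loci, too few for a test. Os02g0278700, named kaurene synthase A, was at -0.17 and 0.66 and copalyl diphosphate synthase Os04g0178300 at -0.89 and -2.57. The pattern missed most measured loci of the phytoalexin clusters in the closing section. There, 6 of 6 loci on chromosome 4 and 7 of 10 on chromosome 2 were 2-fold lower at 0.2 mM.

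Lists for detoxification were higher in part. UDP-glycosyltransferases had a median of 0.18 ± 0.049 at 0.05 mM and 0.052 ± 0.015 at 0.2 mM over 132 loci and passed camera (limma adjusted p = 0.00503 preset, adjusted p = 0.826 with an estimated correlation). Of its members 1 rose over all probes and, adjusted over the list alone, 25 rose and 1 fell. Glutathione S-transferases had medians of 0.12 and 0.087 over 64 loci (limma adjusted p = 0.128). In this list 3 loci at 0.05 mM and 7 at 0.2 mM were 2-fold higher and 0 lower, 2 rose over all probes and 9 when adjusted over the list alone. Its name pattern missed 11 loci named GST, with medians of 0.40 and 0.54, so the list understates the family. Of these, 2 were 2-fold higher and 0 lower at each dose, and 1 rose over all probes. Cytochromes P450, oxidases of plant secondary metabolism, had medians of 0.017 and -0.19 over 215 loci (limma adjusted p = 0.0508), with 17 loci 2-fold lower at 0.2 mM, among them Os04g0180400 at -2.80. In the list 1 locus fell over all probes, and 38 fell and 26 rose when adjusted over the list alone. The name pattern missed 34 other P450-named loci, of which Os11g0289700 (mean -1.09) and Os10g0515900 (mean -0.91) fell and Os11g0138300 (mean 1.10) rose over all probes (limma adjusted p = 0.0466 for each). Among 113 class III peroxidases (medians 0.037 and 0.070, limma adjusted p = 0.513), 11 loci were 2-fold higher and 7 lower at 0.2 mM. The lower ones include 2 of another kind by name, an animal haem peroxidase (Os12g0448900) at -1.40 and a fungal lignin peroxidase (Os07g0694300) at -1.29. Over all probes 3 rose and 1 fell, against 19 and 12 when adjusted over the list alone. ABC and MATE transporters had medians of -0.080 and -0.050 over 84 loci (limma adjusted p = 0.112, 1 fell over all probes, 6 rose and 12 fell when adjusted over the list alone). Oxidant removal had medians of 0.039 and 0.043 over 47 loci (limma adjusted p = 0.348), the latter -0.013 with median centring. Peroxiredoxin Os07g0638400 was the 1 member that rose, over all probes and over the list alone.

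Nutrient and primary metabolism lists were mostly below the control at 0.2 mM. Amino acid and peptide transport had medians of -0.003 and -0.22 over 45 loci, the former 0.016 with Agilent's processed signals. Oligopeptide transporter Os02g0650300 was at -1.09 and -2.08. Phosphate and potassium transport had medians of -0.064 and -0.13 over 68 loci, with a potassium transporter (Os01g0930400) at -0.55 and -1.64. Carbon fixation had -0.20 and -0.17 over 28 loci, with phosphoribulokinase Os04g0280200 at -0.70 and -0.22. These 3 lists passed camera as lower (limma adjusted p = 0.0136, 0.00812 and 0.0136 preset), and adjusted p = 0.826 for each with an estimated correlation, which could hardly pass any list. Over all probes 1 acid phosphatase (Os05g0191500) of the phosphate list fell, also when adjusted over the list alone, and 0 loci of the other 2 lists passed either way. Nitrogen uptake and assimilation had medians of 0.024 and -0.11 over 38 loci (limma adjusted p = 0.0508, 0.0399 with median centring, 1 fell over all probes and 4 when adjusted over the list alone). Sugar and starch genes had 0.011 and -0.059 over 73 loci (limma adjusted p = 0.269, 0 over all probes, 1 rose and 5 fell when adjusted over the list alone). Iron and metal homeostasis, the list of the nicotianamine synthases, had medians of 0.035 and -0.072 over 104 loci (limma adjusted p = 0.386, 0 over all probes, 2 rose and 6 fell when adjusted over the list alone). Photosynthetic light reactions had medians of -0.060 and 0.047 and a mean of -0.031 over 78 loci (limma adjusted p = 0.595, 0 over all probes, 3 rose and 7 fell when adjusted over the list alone).

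Purine metabolism and salvage, the pathway nearest to AHX in structure, had medians of 0.10 and 0.088 over 25 loci, with 0 loci 2-fold at either dose. Xanthine dehydrogenase (Os03g0429800), which oxidises purines, was at -0.30 ± 0.067 and -0.11 ± 0.023 (limma adjusted p = 0.297). The adenine phosphoribosyltransferases, salvage enzymes, were at 0.81 and 0.72 (Os02g0613900) and -0.51 and -1.23 (Os07g0484800), and adenosine kinase Os02g0625500 was at 0.35 and 0.63. The list did not pass (limma adjusted p = 0.359). Over all probes 0 members passed limma, and adjusted over the list alone 2 rose and 1 fell. The name pattern missed Os05g0228000, of the family named purine and other phosphorylases, at -1.67 and -2.29, which fell over all probes (limma adjusted p = 0.0466). It also missed Os02g0663900, named a phosphoribosyltransferase fragment, at 1.02 and 0.92, which rose (limma adjusted p = 0.0466). Neither name settles whether the protein acts on purines. Among 17 aquaporins (medians 0.049 and 0.080, limma adjusted p = 0.585), TIP2.1 Os02g0658100 was at 1.05 ± 0.16 and 2.36 ± 0.065 and the tonoplast aquaglyceroporin Os01g0232000 at 1.36 and -0.40. Over all probes 0 aquaporins passed limma, and 2 rose when adjusted over the list alone.

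Growth, hormone and stress lists did not pass camera, except that ethylene genes passed without the filter (limma adjusted p = 0.0442). Cell wall genes had medians of 0.090 and 0.027 over 112 loci (limma adjusted p = 0.258), and the expansin-related gene Os09g0472900 was the 1 member that fell over all probes. Phenylpropanoid and lignin genes had medians of 0.034 and 0.084 over 72 loci (limma adjusted p = 0.24) and gibberellin genes 0.11 and 0.091 over 19 (limma adjusted p = 0.445). Cytokinin genes had -0.033 and -0.21 over 7 (limma adjusted p = 0.585) and ethylene genes 0.001 and -0.22 over 54 (limma adjusted p = 0.0636), with ACC synthase Os04g0578000, which forms the ethylene precursor, at -0.92 and -1.39. At 0.2 mM 5 ethylene loci were 2-fold lower and 1 higher. Auxin response genes had medians of 0.038 and 0.003 over 92 loci and a mean of 0.018, while camera put the list on the lower side (limma adjusted p = 0.92). NAC factors had medians of 0.006 and -0.058 over 66 loci (limma adjusted p = 0.306), MYB factors -0.005 and 0.045 over 148 (limma adjusted p = 0.776). Heat shock proteins had 0.041 and 0.026 over 166 (limma adjusted p = 0.271), and dehydrins and late embryogenesis proteins 0.053 and -0.099 over 35 (limma adjusted p = 0.559). Apart from that expansin, 0 members of these lists passed limma over all probes. Adjusted over the list alone, 5 cell wall, 14 phenylpropanoid, 5 ethylene, 5 MYB, 1 gibberellin and 1 dehydrin loci rose and 3, 8, 2, 1, 0 and 0 fell.

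Markers of parts that a seedling sample can hold in varying share were listed as well. Root markers had medians of -0.074 and -0.093 over 26 loci (limma adjusted p = 0.422). They include RCc3 genes at 0.95 and 1.77 (Os10g0552800) and 0.57 and 1.36 (Os02g0662000) and the nicotianamine synthases Os03g0307200 and Os03g0307300 far below 0. Another nicotianamine synthase, Os07g0689600, was at 0.19 and -0.056. Seed reserve markers had medians of 0.052 and -0.14 over 24 loci (limma adjusted p = 0.776), with alpha-amylase Os02g0765300 at -0.78 and -2.33. They hold 2 immunoglobulin-like products caught by the name pattern, without which the medians were 0.067 and -0.17 over 22 loci. Pollen and anther markers, as a tissue that seedlings lack, had medians of -0.005 and 0.13 over 14 loci (limma adjusted p = 0.538). An Ole e 1 domain gene (Os01g0726100) at 1.22 and 0.99 was the 1 member that rose over all probes. Adjusted over the list alone, 3 root and 2 pollen loci rose and 6 and 1 fell, and 0 seed reserve loci passed. At 1 dose the median had the opposite sign to the mean and the test for photosynthesis, seed reserve, pollen, cytochrome P450, dehydrin, nitrogen, iron, ethylene, NAC, MYB and sugar lists.

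Of 36 lists with enough loci, 4 passed camera as higher and 7 as lower with a preset correlation. With an estimated correlation 0 lists passed (lowest adjusted p 0.826), and 1 list had an unadjusted p under 0.05. That form has 1 residual degree of freedom, so its result is evidence neither for nor against the preset calls. For cytosolic ribosomal proteins the estimated correlation was -0.00453, yet the unadjusted camera p was 0.0416 against 2.98e-22 preset. Estimated correlations were higher elsewhere (0.386 for WRKY factors), so how far correlation bears on the preset calls stayed open. The camera fit rests on 2 treated samples and 1 control sample. The medians at 0.05 mM of the inhibitor, MYB, NAC, P450, ethylene, pollen and amino acid transport lists turned sign under another scaling or without the filter.

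**Figure D3:**
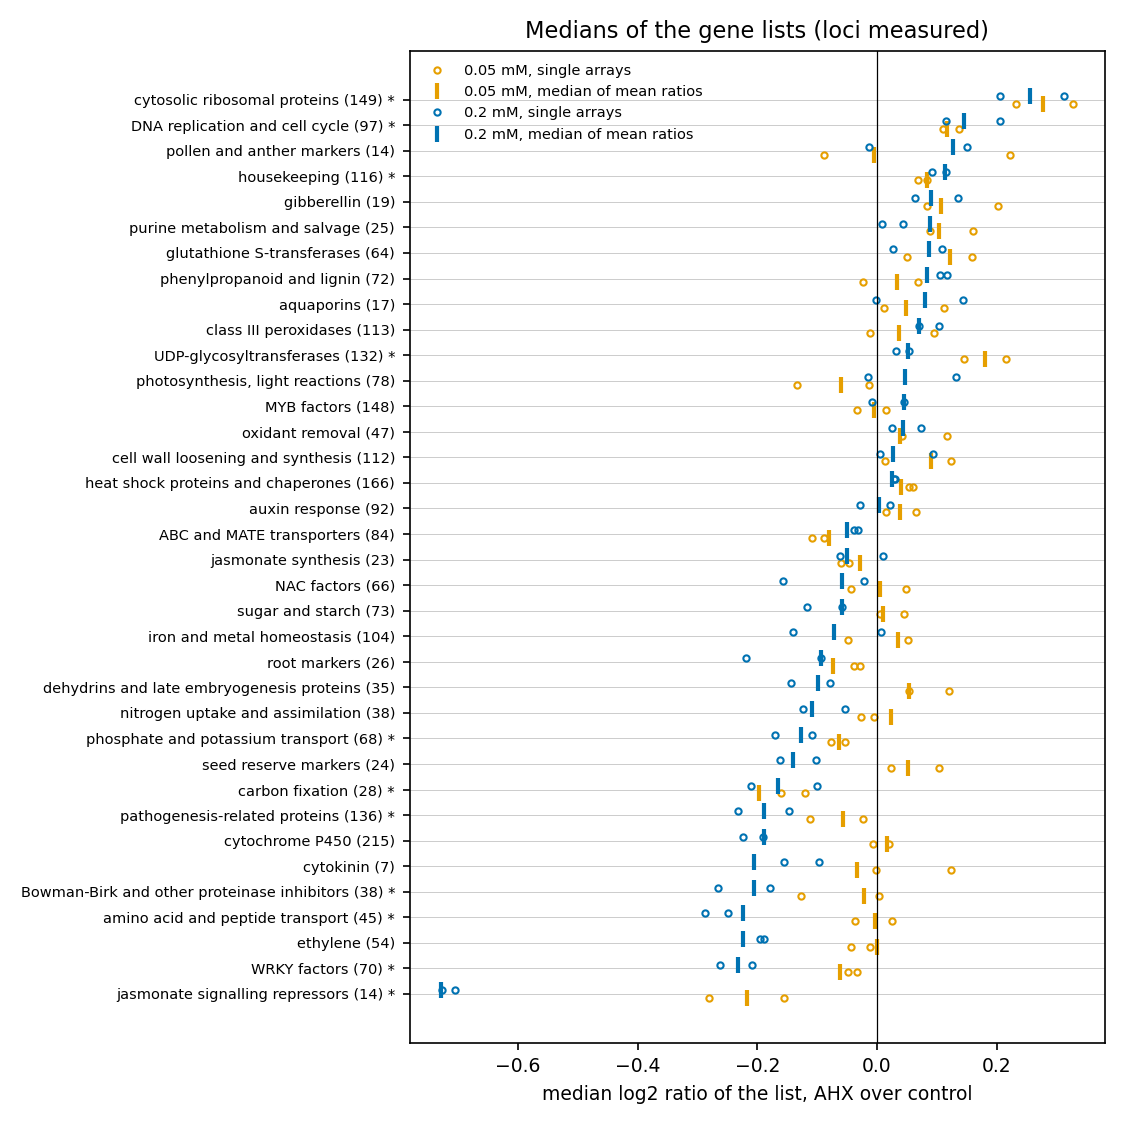
Median log2 ratio of AHX over control for 36 gene lists (horizontal axis, log2 units; measured loci in brackets), with circles for single arrays and bars for the median of the mean ratios, orange at 0.05 mM and blue at 0.2 mM, and an asterisk where camera with a preset correlation passed. Cytosolic ribosomal proteins lie at 0.28 and 0.26, and ZIM-domain repressors of jasmonate signalling at -0.22 and -0.73.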

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

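All tests of explanations in this part were chosen after the values had been seen. None of the differences between doses given here was itself tested, since each dose had 1 treated sample, and each is listed because both arrays of 1 dose lay on the opposite side of 0 from both arrays of the other.

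The homeobox protein Os03g0727000 differed by -3.98 log2 units (0.2 minus 0.05 mM AHX) and the proline-rich protein Os06g0168700 by -4. The lectin Os04g0173800, a carbohydrate-binding protein, differed by -2.98 (1.43 ± 0.068 at 0.05 mM and -1.56 ± 0.081 at 0.2 mM), the gene named for the large Rubisco chain (Os04g0516200) by -2.76 (1.51 ± 0.10 and -1.25 ± 0.006) and alpha-amylase Os08g0473900 by -2.59 (1.21 ± 0.19 and -1.38 ± 0.25).

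These 5 loci were 2-fold higher at 0.05 mM and 2-fold lower at 0.2 mM on every array. A difference in the control RNA between the doses is argued against, since the control channels of the doses differed by at most 0.496 log2 units over the 5 loci and both dye orientations. Noise of single arrays would give ratios that follow the dye as readily as ratios that follow the dose, yet of all probes at 2-fold on all 4 arrays 0 followed the dye at a dose and 10 had opposite directions at the doses. Another difference between the seedling samples of the 2 doses, such as age, water or infection, may account for them as well as the dose, and the 2 cannot be told apart with 1 treated sample per dose. That the response to AHX turns direction between 0.05 and 0.2 mM is a hypothesis that needs further samples at each dose.

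A germin (Os09g0568700), of a family of wall-bound oxidases, differed by -3.84 (0.96 and -2.88) and was not tested for the difference. The xylan endohydrolase Os05g0298700 differed by -3.22 (0.20 and -3.01), also untested. Alpha-amylase 3E (Os08g0473600) differed by -2.66 (2.21 and -0.45), the methyl chloride transferase Os03g0843800 by -2.44 (1.71 and -0.73) and thionin Os06g0512700 by -2.27 (2.14 and -0.14), in no case with a test. Lipoxygenase L-2 (Os03g0738600) went the other way by 1.86 (-0.23 and 1.62), untested. Among gene lists, the median difference was -0.194 over 24 seed reserve markers, -0.117 over 35 dehydrins and late embryogenesis proteins and -0.046 over 73 sugar and starch genes, and these differences were not tested. The seed reserve list holds 2 immunoglobulin-like products caught by the name pattern, and its difference was -0.211 over the 22 loci without them.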

How the results depend on the processing

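Of the checks in this part, a control taken to vary like a treated sample, a random block without a dye term and lists without members of other products were chosen after seeing the data. In all settings 0 called probes turned to the opposite direction, which could not fail on single arrays, and Agilent's processed signals shared 202 of the 205 probes at 0.05 mM, 727 of the 730 at 0.2 mM and 449 of the 449 between doses. Their numbers depended on the setting. At 0.05 mM there were 519 probes with Agilent's processed signals, 518 with the deposited series values, 328 with normexp offset 0 and 296 to 349 on single arrays, 349 without replicate 1 and 296 without replicate 2. At 0.2 mM there were 1533 and 1531 with Agilent's processed and the deposited values (632 and 630 higher, 901 lower in both), and between doses 911 with either and 708 with offset 0. A single array has to pass the 2-fold rule once only, by construction, and for the other shifts the cause was not tested. Limma on the 4 arrays as separate replicates called 27554 probes at 0.05 mM, 28821 at 0.2 mM, 24865 between doses and 6705 over both doses, which measures the spread of arrays and not of plants if swapped arrays carried the same RNA.

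Over both doses the 103 limma calls were the least stable result. Limma made 0 calls with Agilent's processed signals (7636 at an unadjusted p under 0.05, lowest adjusted p 0.0538), 0 with the deposited values (7636, 0.0534), 0 without the intensity trend (7453, 0.0675) and 0 with a control that varies like a treated sample (2049, 0.637), where the standard error is 1.73 times as wide by construction. It made 60 calls without background correction, 189 without a filter, 40 with the submitters' filter, 39 with a robust fit and 3457 with the dye-swap pair as random block without a dye term (correlation 0.383). Fits on single arrays that leave out 1 array made 329 to 2054 calls: 2054 and 1476 without 0.05 mM replicate 1 and 2, and 458 and 329 without 0.2 mM replicate 1 and 2. These fits take the arrays that are left as separate replicates, as does the fit that called 6705 probes on all 4 arrays. Their numbers therefore do not measure how stable the 103 calls are. Apart from the widened error and this change of model, the cause was not tested. Of 65 counts in all, 38 stayed within 1.5 times. With an estimated correlation 0 gene lists passed camera (1 at an unadjusted p under 0.05), which 1 residual degree of freedom would give for almost any lists. With a preset correlation 11 lists passed under Agilent's signals, without a filter and without members of other products, and 12 under median centring. Nitrogen uptake passed under median centring and ethylene without a filter, and proteinase inhibitors no longer passed without a filter. All 103 values of named genes at 2-fold kept their direction and a log2 size of at least 1.11 under 6 scalings. Of all values of named genes under other settings, 757 stayed within the SD between arrays and 251 moved further, and 0 called values reversed. Leaving out saturated probes moves nothing because 0 spots were saturated. A random block with a dye term was not run, as its correlation cannot be estimated from 4 arrays, nor was slide as a block, with 1 slide. No paired analysis was possible because the titles number the doses and not the arrays of a dose, whose replicate numbers here stand for AHX in Cy5 (1) and in Cy3 (2). By their descriptions these arrays are dye swaps, taken as 1 treated and 1 control sample, and the design text leaves that open.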

Other observations

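All families, chromosomal runs and tests in this part were chosen after the values had been seen. Terpene synthases and kaurene enzymes, which build diterpenoid and other terpene skeletons, had median log2 ratios of -0.68 ± 0.012 at 0.05 mM and -1.06 ± 0.19 at 0.2 mM over 22 loci, with 3 and 10 loci 2-fold lower and 0 higher. Germins and germin-like proteins had medians of -0.37 and -0.34 over 22 loci, with 4 and 7 loci 2-fold lower and 4 that fell in limma over both doses. The 5 thionins stood at a median of 2.14 at 0.05 mM and 0.065 at 0.2 mM, which rests on 3 neighbouring loci at 2.14 to 3.08, while the Cp-thionins Os02g0629800 and Os03g0130300 were at 0.25 and 0.40 at 0.05 mM. The 7 alpha-amylases had medians of -0.30 and -1.38, with 2 loci 2-fold higher at 0.05 mM and 4 lower at 0.2 mM. RCc genes, known from root expression, had medians of 0.67 ± 0.024 and 0.51 ± 0.17 over 6 loci, and 11 proteins named GST that the list missed had 0.40 and 0.54. Eggshell-named and glycine-rich proteins, with single members far above the control, had medians of 0.010 and -0.004 over 23 loci. Metallothioneins lay at -0.19 ± 0.24 and -0.26 ± 0.34 over 15 loci, no larger than the spread between arrays. None of the 155 measured microRNA probes was 2-fold at either dose, with log2 ratios of -0.70 to 0.81.

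Genes with large ratios often lay beside each other. Over 25527 measured loci in the order of their identifiers, windows of 5 loci with a median of at least 2-fold formed 6 runs at 0.05 mM and 26 at 0.2 mM. Runs that overlap between the doses count once in the 27 distinct regions. In 100 random orders there were at most 1 run at 0.05 mM and 4 at 0.2 mM. On chromosome 4, copalyl diphosphate synthase Os04g0178300 and its neighbours up to Os04g0180400, with CYP99A cytochromes P450, dehydrogenases and a terpene synthase, were all 2-fold lower at 0.2 mM (6 of 6 loci, medians -0.98 and -2.32). This is the known cluster for momilactones, antimicrobial diterpenes of rice. On chromosome 2, 7 of 10 loci from Os02g0569000 to Os02g0571900, cytochromes P450 and terpene synthases of the phytocassane cluster, were 2-fold lower at 0.2 mM (medians -0.52 and -2.28). Other runs lower at 0.2 mM were alpha-amylases Os02g0765300 to Os02g0765600 (medians -0.61 and -2.33), a run from Os12g0555000 with probenazole-inducible genes (4 of 6 loci, -0.33 and -1.74) and thaumatin-like genes from Os12g0628600 (-0.49 and -1.30). Runs higher at 0.2 mM were that of eggshell-named and hypothetical genes from Os10g0453900 to Os10g0455000 (0.37 and 2.37) and the glutathione S-transferases Os03g0134900 to Os03g0135200 (0.44 and 1.88). Neighbours of 1 family can be near-identical copies that share probe signal, which was not tested.

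Pathogenesis-related genes were lower at 0.2 than at 0.05 mM, with a median difference of -0.187 over 136 loci. A control shared by both doses cannot make this difference, since it enters both ratios alike. The labels do not rule out a separate control for each dose, and the control channels were not compared over these loci. Dye bias or normalization is argued against because the median difference closest to 0 over both dye orientations and 3 scalings was -0.176. A lower share of root tissue at 0.2 mM is not decided: 26 root markers had a median difference of -0.258, but 9 ammonium transporters (-0.42) and 3 nicotianamine synthases (-1.21) lay lower, while 8 loci named RCc or root-specific (0.27) and 6 root hair and COBRA-like loci (0.064) did not. Also open are a dose effect of AHX and another difference between the seedling samples, such as a microbe on some of the plants, which may act alike on these genes and cannot be told apart with 1 treated sample per dose.

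Cytosolic ribosomal protein genes were higher by nearly the same amount at both doses, with a median difference between doses of -0.007. An unusual control sample shared by both doses would give just that and is consistent with it. A bias that follows signal is argued against, because the list lay at percentile 100 among signal-matched random lists at both doses. AHX acting alike at both doses may also account for it, as the lowest of the 4 array medians was 0.206, and the 2 explanations cannot be told apart without a second control sample.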
